A study of Mus musculus with 4 samples.

How the data were processed

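Poly-A RNA of brain tissue from C57BL/6 mice was sequenced as paired-end Illumina libraries, 1 each for young naive, young tumor-bearing, old naive and old tumor-bearing mice. Groups were taken from the labels. The naive samples carry the same GL261 cell line tag as the tumor-bearing ones, and the group tag was followed. The age range given for old mice runs from 8 to 90 weeks, so its lower bound equals that of the young mice. Per the labels' protocols, both a strand-specific and an unstranded library preparation are described without saying which was used, so reads of a gene and of an overlapping antisense gene could not be told apart.

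The deposited values were FPKM, fragments per kilobase of gene scaled to sequencing depth, 1 column per library, per the file headers. Reads were aligned with HISAT2 to mm10, per the submitters' processing notes. The counting program, the annotation, any filter and any pooling of mice were not given in the sources used here. The 54532 Ensembl genes carried no symbols in the files. Symbols, gene types, exon lengths and coordinates came from GENCODE M21, on the same assembly, which named 54409 of them and left 123 without a symbol.

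Depth was recovered from the FPKM values. In each library FPKM times the summed exon length of a gene came in whole steps of what 1 read is worth, which gave the divisor for depth used by the authors (20445811, 19999587, 15646445 and 23253749 fragments in the order above) and the reads of each gene. Of 32867 genes above 0 in any library, 31928 (97.1%) came out whole in all 4, within 0.03 reads or 2e-05 of the value. The recovered fragments in genes were 23267928, 21893368, 19629001 and 19572261. The ratio of divisor to fragments differed by up to 1.49-fold between libraries, while the divisor followed the upper quartile of reads within 5.39%. What the divisor counts was not given in the sources used here. For a gene of 1 kb, 3 reads, the upper limit that a count of 0 allows, corresponded to 0.147, 0.150, 0.192 and 0.129 FPKM.

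The design fixed before the data were examined foresaw counts with a count-based scaling as well as FPKM. Since the values were FPKM, the FPKM branch was used on the deposited scale, and no count test was run. With 1 library per group there was no test between groups. A gene entered a comparison at 1 FPKM or more in at least 1 of its 2 libraries, and log2 ratios were taken of FPKM + 0.1, which understates the difference of low genes. Genes at least 2-fold apart were counted. For the age by tumor difference, the young log2 ratio was subtracted from the old one. Folds were ratios of FPKM without the added 0.1, with exact conditional binomial 95% intervals of the recovered reads. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules and differences between mice are not in them. A fold against 0 reads was given as a lower bound from 3 reads. That bound takes the reads of the other library without counting error, so the exact interval can reach lower.

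In all, 47 gene lists of cell types, brain regions and pathways were fixed before the data were examined. Each list with at least 3 measured members was described by its median and the percentile of that median among 10000 random lists of the same size, matched in 20 bins of mean expression (seed 20), as a description of these libraries. A gene near 0 in 1 library was measured only if it was high in the other, so counts of higher and lower members are partly set by the floor. Of 38 interferon-stimulated genes, 24 entered in old against young naive tissue and 38 in old tumor-bearing against old naive tissue. Of 182 list medians, 6 moved when members with 0 reads were set to 3 reads, by at most 0.55, and 0 changed sign. With genes of 0 reads set to that bound, 641 genes were at least 2-fold higher and 218 lower in young tumor-bearing tissue, 3243 and 5032 in old tumor-bearing tissue, 901 and 658 in old against young naive tissue, and 3046 and 4802 in old against young tumor-bearing tissue.

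Genes named in the text were the 10 highest and 10 lowest of each comparison among genes with established symbols, up to 4 members of each list with the largest absolute log2 ratio, and 16 genes fixed in advance. In the young tumor comparison 9 of the 10 highest and 9 of the 10 lowest were short RNA genes with at most 19 and 11 reads in a library, for which a poly-A library is not made, and in the old tumor comparison 10 of the 10 lowest, with at most 8 reads. In old against young naive tissue they were 10 of the 10 highest and 2 of the 10 lowest (at most 19 and 9 reads), and in the age by tumor difference 5 of the 10 highest and 10 of the 10 lowest (at most 7 and 16 reads). A repeat among protein-coding genes was therefore added after the values were seen, and the short RNA genes are not described singly. Further genes were chosen after their values were seen where the text says so. Some single-gene results are not reported here.

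The procedure was tested on data simulated from the read counts of each comparison, with 200 genes changed by known folds, of which 199 reached the floor in old tumor-bearing against old naive tissue and all 200 in the others. In the simulation of young tumor-bearing against young naive tissue (15131 genes), 100% of genes raised 3-fold and 94% of those lowered 3-fold passed 2-fold, the intervals covered the true ratio for 95.4% of genes, and 310 of 14931 unchanged genes passed 2-fold, 12 of them protein-coding. For old tumor-bearing against old naive tissue (15601 genes) the values were 98%, 96% and 95.3%, with 345 of 15402 unchanged genes, 13 of them protein-coding. For old against young naive tissue (14995 genes) they were 100%, 100% and 95.7%, with 379 of 14795, 15 protein-coding. For old against young tumor-bearing tissue (15668 genes) they were 100%, 98% and 95.3%, with 348 of 15468, 17 protein-coding. These simulations hold counting error and no difference between mice.

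Alternatives fixed before the data were examined were median-of-ratios scaling, floors of 0.1 and 5 FPKM and no floor, pseudocounts of 0.01 and 1 FPKM, and scaling without mitochondrially encoded and the 50 highest genes. Scaling by fragments in genes, scaling to equal FPKM totals, protein-coding genes only, and an exact interval beyond 2-fold on the recovered reads were added after the data were seen. Close copies (granzymes, H2-Q genes, Gapdh and its pseudogenes) are given as uncertain. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.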

Results

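RNA sequencing of mouse brain tissue was compared in 4 groups of C57BL/6 animals that crossed age (young, old) with the presence of a brain tumor (naive, tumor-bearing). The tumor-bearing mice had been engrafted in the brain with 50000 GL261 cells, a C57BL/6 mouse glioma line widely used as a transplantable model of glioblastoma, and the tissue was taken on day 21. The submitters call the tissue extra-tumoral, that is, brain outside the tumor mass. The young mice were 8 to 12 weeks old. The age range given for the old mice starts at the same lower bound as that of the young ones, so the old group is used here only as labelled. Each group was 1 library, and the number of mice behind it was not given in the sources used here, so no difference below has a replicate check and no test between groups was made. Each statement compares libraries. Values in parentheses after a fold are exact 95% intervals of the ratio of reads, which cover counting error only. Those of the Y to X ratios at the end are normal approximations.

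The files listed 54532 genes with 1 FPKM value each. Recovered reads came to 23267928 fragments in the listed genes of the young naive library, 21893368 in the young tumor-bearing, 19629001 in the old naive and 19572261 in the old tumor-bearing library. Between 14323 and 14994 genes reached 1 FPKM in a library. The number by which the authors divided reads to obtain FPKM was 0.879, 0.914, 0.797 and 1.19 times these fragments, in the same order, so 1 FPKM in the old tumor-bearing library stood for more reads per fragment sequenced than in the other libraries. Mitochondrially encoded genes held 5.51%, 4.72%, 5.44% and 2.12% of the fragments. Transcripts of Xist, the RNA that coats the inactive X chromosome of female cells, had 4, 4, 1 and 4 reads, and the Y-linked Ddx3y was present at 13.9, 13.2, 9.90 and 4.14 FPKM in that order.

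The first comparison asked how brain tissue of young tumor-bearing mice differed from that of young naive mice. Antigen presentation, interferon-stimulated, complement and reactive astrocyte genes were higher in the tumor-bearing library, while neuronal, oligodendrocyte and endothelial medians were within 2-fold. Of 38 listed interferon-stimulated genes, 33 were over the floor of 1 FPKM. Of these, 30 were at least 2-fold higher and 0 lower (median log2 ratio 2.15). The MHC class II list, whose products present peptides to CD4 T cells, had 7 of 8 members at least 2-fold higher (median 2.94), and the MHC class I list 15 of 18 (median 1.70). All 3 medians exceeded those of 10000 random lists matched on expression. Over all genes above the floor, 783 of 15500 were at least 2-fold higher and 286 lower, and the median log2 ratio of all genes was -0.01. Most of these were not protein-coding. Among the 12875 protein-coding genes alone, a restriction chosen after the values were seen, 298 were higher and 45 lower.

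Within the MHC lists, Cd74, the invariant chain of MHC class II (ENSMUSG00000024610, mm10 chromosome 18, 60803848 to 60812652), was listed at 6.04 FPKM in the naive and 98.5 FPKM in the tumor-bearing library, 16.3-fold higher (14.2 to 18.9). H2-Aa was 20.6-fold higher (16.7 to 25.8) and H2-Eb1 12.9-fold (10.7 to 16.0). Nlrc5, the transactivator of MHC class I genes, was 40.2-fold higher (22.8 to 78.4), Tap1, a subunit of the peptide transporter, 13.7-fold (10.4 to 18.3), and B2m, the MHC class I light chain, 2.99-fold (2.83 to 3.17). H2-Q6 was 31.5-fold higher (18.2 to 59.6), but the H2-Q genes are close copies whose reads can be split between them, so single members are uncertain. Cxcl10, an interferon-induced chemokine, had 4 reads against 166 (42.4-fold, 16.3 to 158), and Gbp2, an interferon-induced GTPase, was 12.7-fold higher (10.2 to 16.0). The list of chemokines and inflammatory cytokines had 7 of 10 measured members at least 2-fold higher (median 2.15), above all random lists. Its median turned to -0.10 when only genes of at least 5 FPKM were kept, and all 7 members that were higher lay below that level.

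In the complement list 6 of 12 measured members were at least 2-fold higher and 0 lower (median 1.03). C3, the central complement component, was 40.9-fold higher (27.7 to 62.9) and C4b 7.73-fold (7.0 to 8.54). The reactive astrocyte list had 13 of 22 members at least 2-fold higher and 1 lower (median 1.22). This list is not separate from the others in any comparison. It shares Cxcl10 and Gbp2 with the interferon-stimulated list, Psmb8 with MHC class I and Serping1 with complement. Vim, Cd44 and Timp1 are also on the extracellular matrix list. Gfap, the intermediate filament of astrocytes, was 2.43-fold higher (2.35 to 2.51), Serpina3n 3.35-fold (2.99 to 3.77) and Lcn2 50.7-fold (21.4 to 158), whereas Hspb1, a small heat shock protein on the same list, was 3.10-fold lower (2.58 to 3.73). The astrocyte identity list stood at a median of -0.01. The homeostatic microglia list had no member 2-fold apart (median 0.24), and P2ry12, a receptor of resting microglia, was at 11.7 and 11.9 FPKM. The disease-associated microglia list had 5 of 19 members at least 2-fold higher (median 0.39), Gpnmb among them (7.5-fold, 5.79 to 9.85). Cst7 had 0 reads in the naive and 27 in the tumor-bearing library, at least 9.20-fold higher. Itgax, an integrin of dendritic cells and activated microglia, was at least 22.8-fold higher, with 0 and 67 reads.

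Proliferation and matrix genes were also higher. The cell cycle list had 10 of 20 measured members at least 2-fold higher and 0 lower (median 1.01), at low levels. Mki67 was at 0.18 FPKM in the naive and 1.19 FPKM in the tumor-bearing library (6.60-fold, 4.66 to 9.61), and Top2a at 0.185 and 2.11 FPKM (11.4-fold, 8.03 to 16.7). The extracellular matrix and mesenchymal list had 9 of 25 members at least 2-fold higher (median 0.85), with Lgals3 11.5-fold higher (7.62 to 18.1). Cdkn2a, the locus of the cell cycle inhibitors p16 and p19 and a marker of senescent cells (ENSMUSG00000044303, mm10 chromosome 4, 89274471 to 89294653), had 4 and 51 reads (13-fold, 4.79 to 49.7), while Cdkn1a, which encodes p21, was 1.27-fold lower (1.13 to 1.44). The senescence and secretory phenotype list as a whole had 3 of 21 members at least 2-fold higher and 0 lower (median 0.15). Cd274, which encodes the checkpoint ligand PD-L1, was 4.11-fold higher (2.95 to 5.83), and 4 of 10 measured members of the immune checkpoint and suppression list were at least 2-fold higher (median 0.56). Ido1, which starts tryptophan breakdown, did not differ beyond counting error (1.35-fold, 0.778 to 2.37), and the tryptophan and kynurenine list had 1 of 5 members 2-fold apart. Monocyte and macrophage genes had 3 of 8 members at least 2-fold higher and 0 lower (median 0.75), above the middle 95% of random lists. Few lymphocyte genes reached the floor. The B and plasma cell list had 1 of 3 measured members higher (median 0.75), also above that range. Of the T cell list 5 members were measured and 1 was higher, Trac at 3.14-fold (1.69 to 6.21). Cd4 was equal within counting error (1.01-fold lower, 0.775 to 1.33). Cd8a had 0 and 18 reads, at least 6.13-fold higher, and stayed below the floor. Of the pituitary hormone list only Lhb reached the floor, with 4 and 14 reads.

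The highest log2 ratio of FPKM + 0.1 among named protein-coding genes was that of Krt8, a keratin of simple epithelia (ENSMUSG00000049382, mm10 chromosome 15, 101996698 to 102004482), listed at 0.375 FPKM in the naive and 23.1 FPKM in the tumor-bearing library (61.5-fold, 37.1 to 110). Epcam, an epithelial adhesion molecule, had 2 and 141 reads (67.0-fold, 19.6 to 601). In the other direction stood neuropeptides of the hypothalamus, a region whose list had 5 of 8 measured members at least 2-fold lower (median -1.77), below all random lists. Hcrt, the orexin precursor, had 124 reads in the naive and 2 in the tumor-bearing library (60.6-fold lower, 16.4 to 506), Oxt, the oxytocin precursor, 52 and 3 (17.0-fold lower, 5.49 to 84.9), and Pmch 69 and 10 (6.75-fold lower, 3.46 to 14.7). The heat shock and protein folding list was lower, with 0 of 21 members at least 2-fold higher, 1 lower and a median of -0.46, below all random lists. The striatum list had no member 2-fold apart, but its median of -0.36 lay below all random lists, and the pan-neuronal list, with 0 of 18 members 2-fold apart, had a median of -0.22, just below the middle 95% of them. The medians were -0.10 for excitatory neurons, -0.19 for inhibitory neurons, -0.05 for cerebellum, -0.10 for oligodendrocytes and 0.02 for endothelial cells.

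The second comparison was that of old tumor-bearing with old naive tissue, and it spanned a far wider range. Immune, interferon, cell cycle and matrix genes were much higher in the tumor-bearing library, and neuronal and synaptic genes were several-fold lower. All 38 interferon-stimulated genes were at least 2-fold higher (median log2 ratio 5.17), as were all 18 genes of the MHC class I list (median 3.78) and all 11 measured genes of the MHC class II list (median 4.0, or 3.46 when a member with 0 reads was set to the level of 3 reads). The cell cycle list had 29 of 31 members at least 2-fold higher (median 4.99). The synaptic list had 24 of 24 members at least 2-fold lower (median -2.56) and the pan-neuronal list 17 of 18 (median -2.48). In total 3395 of 16488 genes were at least 2-fold higher and 5171 lower. The median log2 ratio over all genes was -0.31 on the deposited scale, and the split depended on scaling. It was 4639 higher and 3847 lower with median-of-ratios scaling (median of all genes shifted by 0.37), 5366 and 3217 when scaled by fragments in genes (0.56), 4718 and 3596 with equal FPKM totals (0.42), and 4196 and 4071 when mitochondrial and the 50 highest genes were left out of the total (0.27). All these shifts went upward, so a negative list median near 0 has no fixed direction, while positive list medians kept their sign. Negative medians turned as far out as -0.70, that of the hypothalamus list.

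The highest ratio of all belonged to H19, a maternally expressed long noncoding RNA of the imprinted Igf2 region (ENSMUSG00000000031, mm10 chromosome 7, 142575529 to 142578143), with 2 reads (0.052 FPKM) in the naive and 142841 reads (2497 FPKM) in the tumor-bearing library. Cxcl10 was at 0.114 and 237 FPKM. Csn3, a milk casein gene, had 0 and 6417 reads, and Ubd, an interferon-inducible ubiquitin-like protein, 0 and 517 (at least 116-fold higher). Granzymes F and G had 0 reads in the naive library and 25.6 and 26.0 FPKM in the tumor-bearing one, each at least 123-fold higher, and their single values are uncertain because granzymes D to G are close copies. Among members of the immune lists, Cd74 was 84.2-fold higher (73.4 to 97.1), B2m 14.9-fold (14.2 to 15.7), reaching 1684 FPKM, Tap1 54.0-fold (45.4 to 64.7), and Psmb8, a subunit of the immunoproteasome, 71.5-fold (56.0 to 92.0). The chemokine list had 14 of 17 measured members at least 2-fold higher and 2 lower (median 4.65).

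Lymphoid and myeloid lists were higher as well. The cytotoxic T and NK cell list had all 10 measured members at least 2-fold higher (median 4.41). Genes nearly absent from naive tissue are measured only if they are high in tumor-bearing tissue, so such counts are partly fixed by the floor. Gzmb, granzyme B, had 0 and 574 reads (at least 129-fold higher), and Ccl5 was 110-fold higher (46.9 to 339). The T cell list had 12 of 16 members higher and 2 lower (median 3.29), with Trac 24.6-fold higher (9.39 to 91.3) and Cd4 1.82-fold lower (1.5 to 2.21). Cd8a was 29.6-fold higher (12.5 to 92.1) at 2.60 FPKM. The B and plasma cell list had 7 of 9 members higher (median 3.19), which lay within the middle 95% of random lists. Monocyte and macrophage genes had 12 of 14 members higher (median 3.64), with Arg1 60.4-fold higher (25.7 to 187). The neutrophil list went both ways (2 of 5 higher, 2 lower, median -0.77). Disease-associated microglia genes had 15 of 20 members higher (median 2.61) and complement genes 12 of 15 (median 2.45), C3 at 88.0-fold (58.6 to 139) and C4b at 4.58-fold (4.34 to 4.83). The homeostatic microglia median was -0.06 on the deposited scale and 0.32 under median-of-ratios scaling, and P2ry12 was 1.83-fold lower (1.62 to 2.06). In the immune checkpoint list 14 of 16 members were higher (median 2.69). Cd274 was 18.3-fold higher (14.4 to 23.6), Lgals9 22.9-fold (18.7 to 28.4), and Pdcd1, which encodes PD-1, had 1 and 126 reads. Ido1 stood apart from these, 4.71-fold lower (2.73 to 8.5), in a tryptophan and kynurenine list with 4 of 8 members higher and 2 lower (median 0.60).

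Cdkn2a was 109-fold higher (57.3 to 239), at 0.491 and 53.5 FPKM, and Cdkn1a 5.31-fold (4.75 to 5.96). The senescence and secretory phenotype list had 21 of 32 members at least 2-fold higher and 5 lower (median 2.25), with Timp1 37.8-fold higher (25.7 to 58.1). The p53 target list had 5 of 18 higher and 3 lower (median 0.58). Mki67 was 141-fold higher (92.0 to 228), at 0.133 and 18.8 FPKM. The extracellular matrix and mesenchymal list had 21 of 26 members higher and 1 lower (median 2.62), with Lgals3 136-fold higher (79.5 to 256). The heat shock and protein folding list had 9 of 21 higher and 3 lower (median 0.52). The reactive astrocyte list had 21 of 25 members higher and 0 lower (median 2.67), with Serpina3n 43.1-fold (38.0 to 48.9) and Gfap 3.96-fold higher (3.80 to 4.12), while the astrocyte identity list had 14 of 18 lower and 1 higher (median -1.59), with the glutamate transporter Slc1a2 4.98-fold lower (4.89 to 5.07).

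Neuronal genes were lower across classes. The excitatory list had 15 of 16 members at least 2-fold lower (median -2.59) and the inhibitory list 15 of 16 (median -2.41). Snap25, a synaptic vesicle fusion protein, was 7.47-fold lower (7.28 to 7.67), Rbfox3, which encodes NeuN, 7.79-fold (7.35 to 8.26), and Tbr1, a cortical transcription factor, 13.7-fold (12.2 to 15.4). The striatum list had 14 of 14 members lower (median -3.18), with the dopamine receptor gene Drd1 15.4-fold lower (12.6 to 19). The thalamus list did not share this (3 of 11 higher, 0 lower, median 0.34), and the hippocampus list went both ways (3 of 12 higher, 5 lower, median 0.33). The choroid plexus list was higher in 11 of 12 members (median 2.96), with Ttr, the thyroid hormone carrier made by that epithelium, at 4.88 FPKM in the naive and 445 FPKM in the tumor-bearing library. Ttr was at 402 FPKM in the young naive and 383 FPKM in the young tumor-bearing library, so the old naive library was the low one. Oligodendrocyte genes had 2 of 20 members higher and 1 lower, with a median of -0.50 that became 0.07 when scaled by fragments in genes. Sox10, a transcription factor of that lineage, was 6.38-fold higher (6.00 to 6.78). The endothelial median of -0.36 became 0.01 under median-of-ratios scaling. Pericyte (median -1.31), circadian clock (median -1.89), cholesterol synthesis (median -1.13) and immediate early genes (median -1.42) were lower, and all 13 mitochondrially encoded genes were at least 2-fold lower (median -1.94). The nuclear oxidative phosphorylation list had 0 of 27 higher and 4 lower (median -0.45, or 0.12 when scaled by fragments in genes). The ependymal median was 0.30, the hypothalamus median -0.70 (0.17 when scaled by fragments in genes), the hypoxia and glycolysis median -0.62, the glucocorticoid response median -0.63, the fibroblast and meningeal median -0.80, the oligodendrocyte precursor median -1.11 (7 of 12 lower) and the red blood cell median -1.89 (5 of 5 lower), each inside the middle 95% of random lists.

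**Figure D1:**
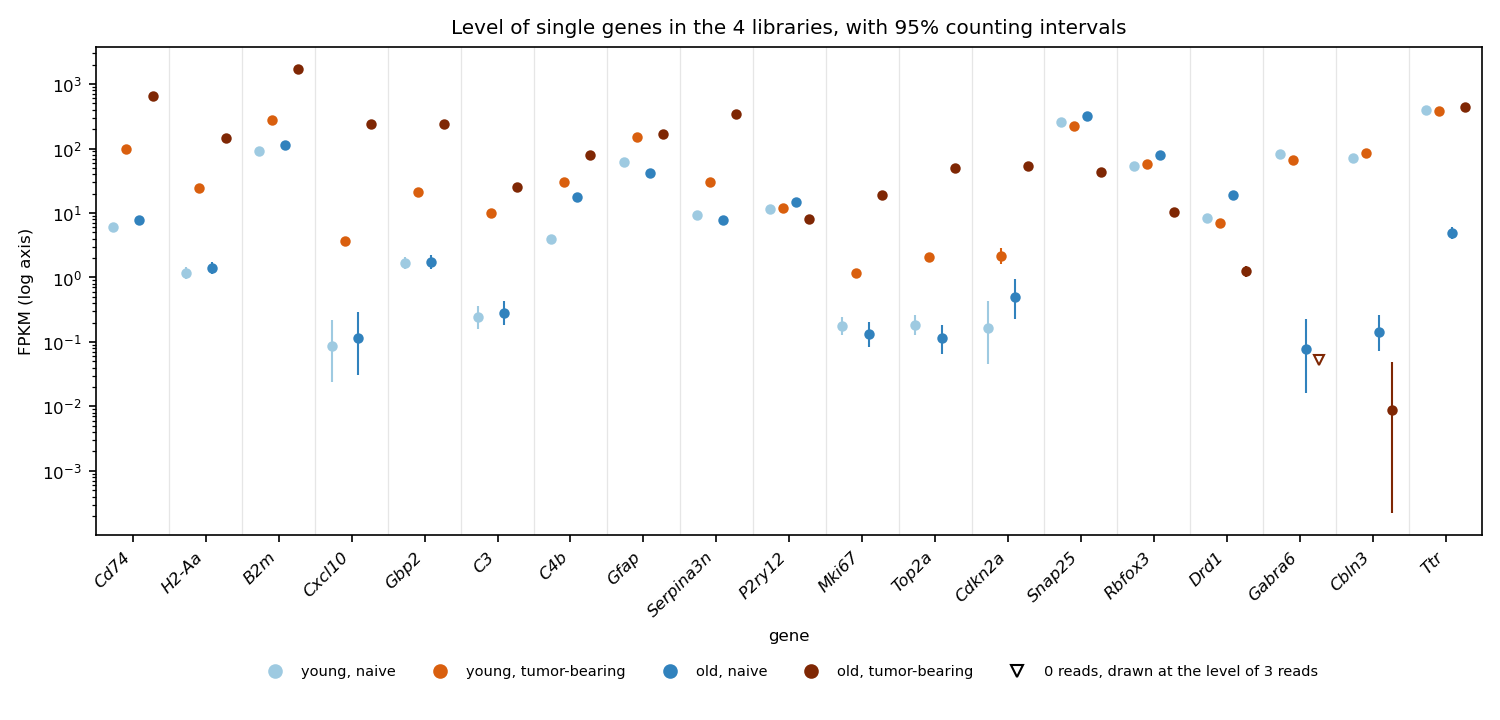
FPKM (log axis) of 19 genes in the 4 libraries, each point 1 library with the exact 95% Poisson interval of its recovered reads, and open triangles for 0 reads drawn at the level of 3 reads. Cd74 stood at 6.04 and 7.84 FPKM in the naive libraries and at 98.5 and 660 FPKM in the tumor-bearing ones, Snap25 was lowest in the old tumor-bearing library at 43.5 FPKM, and Gabra6 and Cbln3 were near 0 in both old libraries.

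The third comparison set old against young naive tissue, both without a tumor. Lists of brain regions differed between these libraries. An effect of age therefore cannot be told apart from a difference in the part of the brain sampled, for any gene or list below. Genes of the cerebellum, thalamus and choroid plexus were far lower in the old library, while the medians of the striatum, excitatory neuron, MHC class I and interferon-stimulated lists lay above those of all random lists, with most of their members within 2-fold. The cerebellum list had 13 of 14 members at least 2-fold lower (median log2 ratio -4.47) and the thalamus list 8 of 11 (median -1.19). The choroid plexus list had 10 of 10 members lower (median -2.66). The striatum list had 4 of 14 members at least 2-fold higher and 0 lower (median 0.88). In all, 1035 of 15419 genes were at least 2-fold higher and 760 lower, or 415 and 391 among protein-coding genes. The split again depended on scaling, with 710 higher and 860 lower when scaled by fragments in genes, 612 and 1015 with equal FPKM totals, and 755 and 869 without mitochondrial and the 50 highest genes in the total. Median-of-ratios scaling kept more genes higher, with 910 and 753. The median of all genes was 0.06 on the deposited scale and shifted by -0.14, -0.22, -0.13 and -0.03 under those scalings.

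Gabra6, a GABA receptor subunit of cerebellar granule cells (ENSMUSG00000020428, mm10 chromosome 11, 42306437 to 42321072), was at 81.5 FPKM in the young and 0.077 FPKM in the old library (4147 and 3 reads), and Cbln3, a granule cell cerebellin, at 70.8 and 0.144 FPKM (490-fold lower, 274 to 982). Pcp2, a marker of Purkinje cells, was 151-fold lower (64.6 to 467). Ttr was 82.4-fold lower (67.3 to 103). Among thalamic and brainstem-related genes, Zic1 was 13.5-fold lower (12.1 to 15.1), Slc17a6, the vesicular glutamate transporter of subcortical neurons, 7.64-fold (6.70 to 8.75), and Tph2, the enzyme of serotonin synthesis in the raphe, 19.4-fold (11.8 to 34.2). The hypothalamus list had 5 of 8 members lower (median -2.0), Hcrt 31.6-fold (10.6 to 155) and Avp 8.93-fold (3.90 to 25.2). The hippocampus list had 6 of 12 lower (median -0.99), and the ependymal list 3 of 9 lower (median -0.72). Tbr1 was 2.45-fold higher (2.30 to 2.60), Drd1 2.33-fold (2.11 to 2.58) and Camk2a 2.06-fold (2.03 to 2.08). The excitatory list had 5 of 16 members higher and 1 lower (median 0.63), and the inhibitory list 2 of 16 higher and 3 lower (median 0.33). The pan-neuronal median was 0.21 (-0.02 with equal FPKM totals), with no member 2-fold apart. Immediate early genes were higher in 7 of 20 members (median 0.82), with Arc 2.55-fold higher (2.41 to 2.69). The oligodendrocyte median was -0.46 and the astrocyte identity median -0.26, both below the middle 95% of random lists. The heat shock and protein folding list had 0 of 21 members at least 2-fold higher and 3 lower (median -0.38), below all random lists.

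On the immune side of this comparison, the MHC class I list had 4 of 16 members at least 2-fold higher and 0 lower (median 0.75) and the interferon-stimulated list 4 of 24 (median 0.44), both above all random lists, and the complement list 2 of 9 (median 0.46). The MHC class II list had 0 of 7 members 2-fold apart, with a median of 0.37 inside the middle 95% of random lists. Lists with few measured members lay above that range, namely neutrophils (3 of 4 higher, median 1.71), B and plasma cells (2 of 3, median 1.23, which changed sign with a floor of 0.1 FPKM) and T cells (2 of 4, median 0.80). Tap1 was 3.01-fold higher (2.18 to 4.20), C4b 4.45-fold (4.0 to 4.95) and Cd4 2.75-fold (2.19 to 3.46). C3 (1.16-fold, 0.630 to 2.11) and Mki67 (1.35-fold lower, 0.769 to 2.42) did not differ beyond counting error. Cdkn2a had 4 and 9 reads (2.94-fold, 0.821 to 13.1), so an age difference was not detectable at this depth, and Cdkn1a was 1.35-fold lower (1.18 to 1.54). The senescence list had 0 of 19 members 2-fold apart (median 0.23). Ido1 was 2.98-fold higher (1.83 to 4.98), with 25 and 57 reads. Gfap was 1.45-fold lower (1.38 to 1.52), and the cell cycle list had 1 of 8 members higher and 1 lower (median 0.05). Col6a1, a collagen chain, was 4.70-fold higher (4.31 to 5.12).

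The fourth comparison set the old tumor-bearing library against the young tumor-bearing one. Here too, age cannot be told apart from the part of the brain sampled. All 38 interferon-stimulated genes (median log2 ratio 3.49) and all 18 MHC class I genes (median 2.85) were at least 2-fold higher in the old library, as were 30 of 31 cell cycle genes (median 3.73), 21 of 31 senescence and secretory phenotype genes (median 2.08, 3 lower) and 18 of 26 extracellular matrix genes (median 2.25, 0 lower). All 24 synaptic genes were at least 2-fold lower (median -1.96), and so were all 14 cerebellar genes (median -5.02) and all 14 striatal genes (median -1.93). Counts were 3155 genes higher and 4941 lower of 16562, which became 4516 and 3379 under median-of-ratios scaling and 4528 and 3509 when scaled by fragments in genes. With equal FPKM totals they were 3678 and 4417, and without mitochondrial and the 50 highest genes in the total 3431 and 4611, so more genes stayed lower. The median of all genes was -0.28 on the deposited scale, and the 4 scalings shifted it by 0.39, 0.37, 0.15 and 0.08.

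Single genes higher in this comparison included Cdkn2a, 24.6-fold (18.6 to 33.2), Mki67, 15.8-fold (13.9 to 18.1), Serpina3n, 11-fold (10.4 to 11.7), Cd274, 8.90-fold (7.64 to 10.4), and Cd74, 6.70-fold (6.46 to 6.95), while Gfap was 1.12-fold higher (1.10 to 1.15). H19 was 382-fold higher (342 to 427). Tex101, known from testis, had 0 and 1613 reads (at least 462-fold higher), and Emilin1, an extracellular matrix glycoprotein, was 107-fold higher (90.0 to 127). Ido1 was 2.13-fold lower (1.17 to 4.02). Snap25 was 5.20-fold lower (5.07 to 5.34) and Rbfox3 5.61-fold (5.29 to 5.95). The choroid plexus list had 2 of 13 members higher and 1 lower (median 0.11). The oligodendrocyte list had 1 of 20 higher and 7 lower (median -0.84), and the homeostatic microglia median was -0.18 (0.22 under median-of-ratios scaling). The other lists of this comparison are in the plot of list medians.

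**Figure D2:**
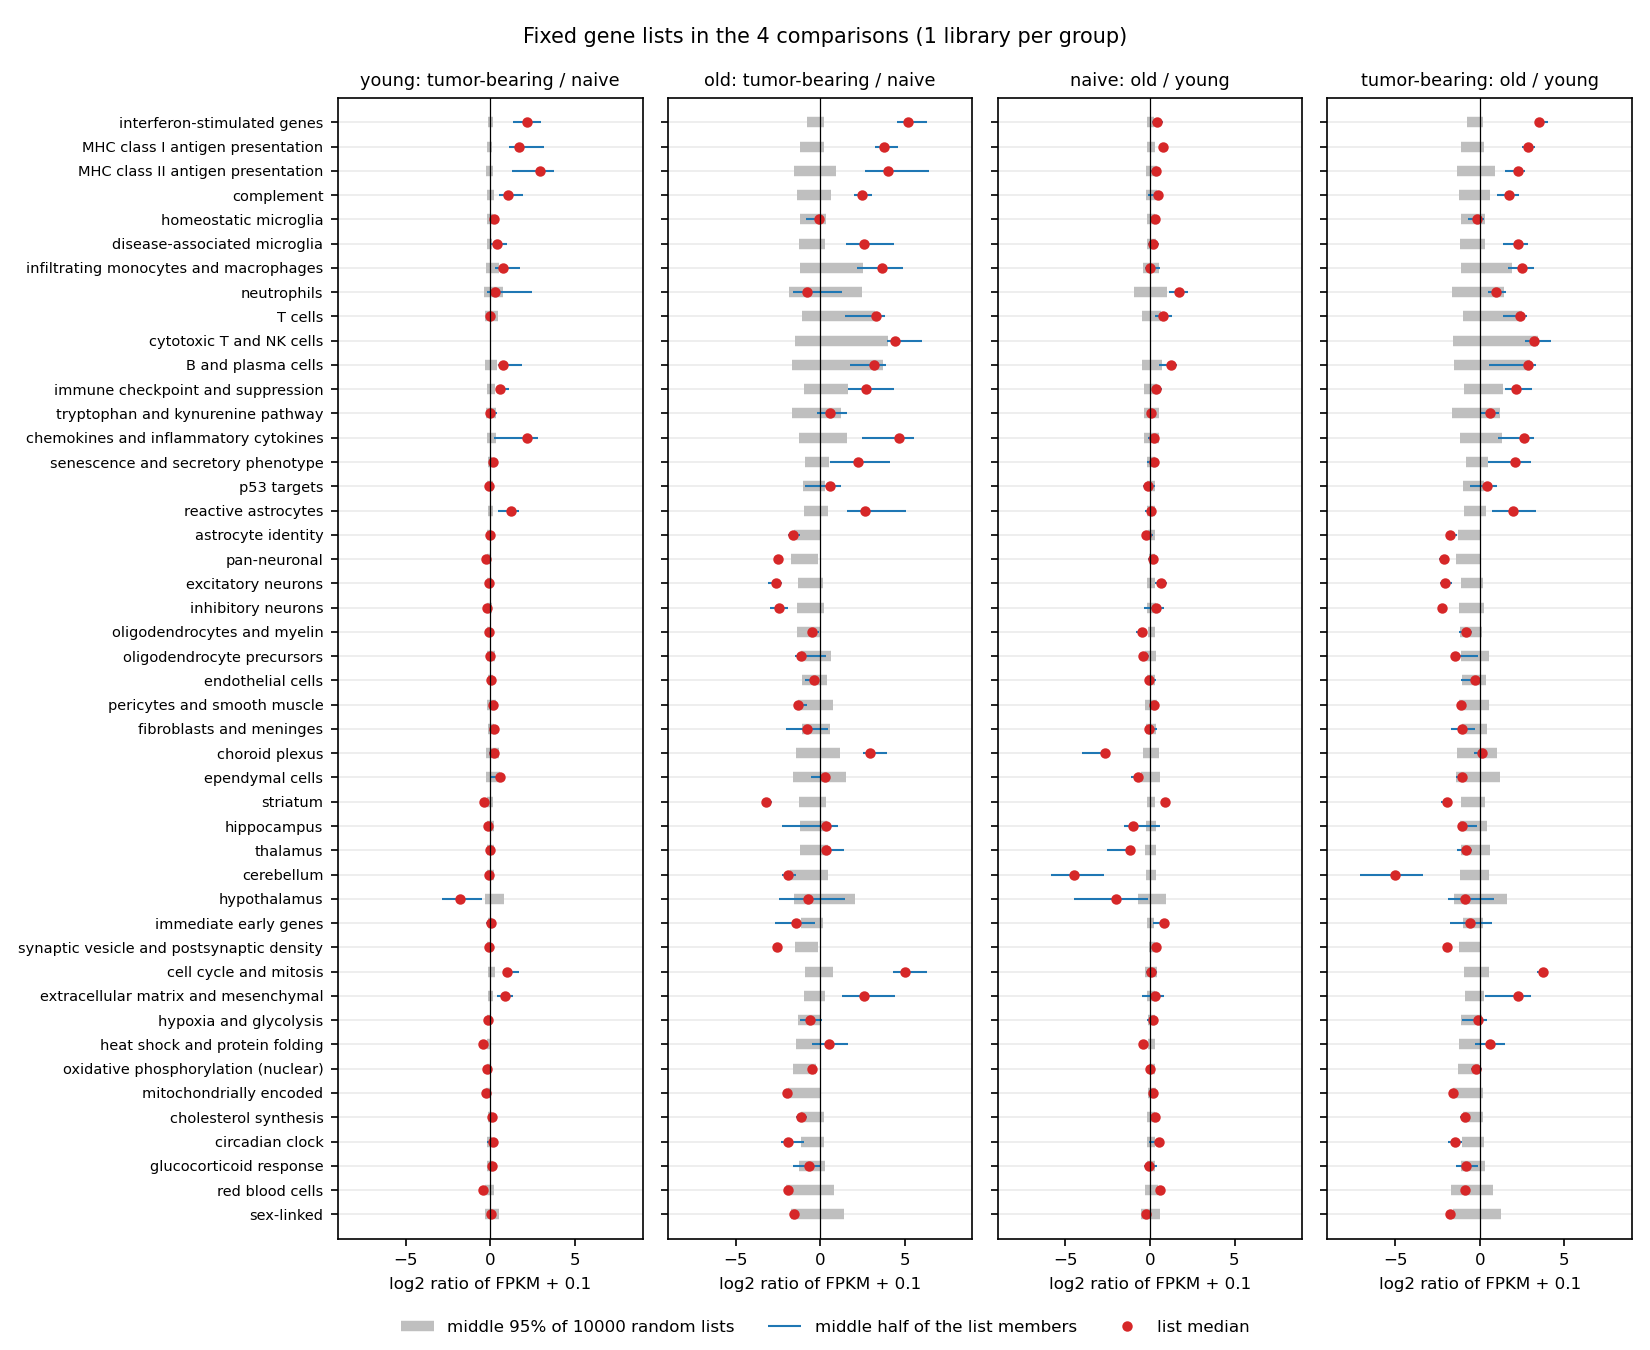
Median log2 ratio of FPKM + 0.1 (red points) of the fixed gene lists in the 4 comparisons, with the middle 50% of the list members (blue lines) and the middle 95% of medians of 10000 expression-matched random lists (gray bars); lists with fewer than 3 measured members have no point. The interferon-stimulated list lay right of its gray bar in each panel (2.15, 5.17, 0.44 and 3.49), and the cerebellum list lay far to the left in both panels that compare ages (-4.47 and -5.02).

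The design also implies the question of whether the tumor-to-naive ratio differed by age. Since lists of brain regions differed between the libraries, such a difference cannot be told apart from one in the tissue sampled. The log2 ratio of tumor-bearing to naive tissue in old mice minus that in young mice was at least 1 for 3372 of 17441 genes and at most -1 for 5583. Under median-of-ratios scaling the counts were 4834 and 4096, scaled by fragments in genes 5226 and 3799, and with equal FPKM totals 4601 and 4243, while without mitochondrial and the 50 highest genes in the total they were 4014 and 4780, as before with more genes lower. The medians of this difference were 2.92 for interferon-stimulated, 2.07 for MHC class I, 2.26 for MHC class II, 3.79 for cell cycle, 1.70 for senescence and 1.68 for reactive astrocyte genes, each above the middle 95% of random lists, and -2.24 for pan-neuronal, -2.50 for synaptic and -2.82 for striatal genes, each below it. Lists of brain structures went different ways, with medians of 3.80 for the hypothalamus (5 of 9 at least 1, 3 at most -1) and 2.73 for the choroid plexus (11 of 13 at least 1), both above all random lists, while thalamus (0.44), hippocampus (0.46), ependymal (0.12) and cerebellum (-1.27) medians lay inside the middle 95%. For the choroid plexus it was the old naive library that stood apart. The list median of old against young tumor-bearing tissue was 0.11. Ttr was at 402 FPKM in young naive, 383 in young tumor-bearing, 4.88 in old naive and 445 in old tumor-bearing tissue. The hypothalamus median of old tumor-bearing to old naive tissue was itself -0.70 (0.17 when scaled by fragments in genes). That list was also lower in young tumor-bearing and in old naive tissue than in young naive tissue, with several members at few reads. Its 3.80 is thus not a rise in old tumor-bearing tissue alone. Among protein-coding genes the largest differences beside those of the granzymes were those of Csn3, Tex101 and Cytl1, which had 6417, 1613 and 1701 reads in the old tumor-bearing library. Among the lowest were Igfn1 (difference -5.23), Chit1 (-5.11) and Gapdh (-4.55). The value of Gapdh is uncertain, because many processed pseudogenes share its sequence. C4b did not share the difference of the complement list (median 1.15), with ratios of 7.73-fold in young and 4.58-fold in old tissue.

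The 2 tumor comparisons used separate libraries. Among 14547 genes over the floor in both, 565 were at least 2-fold higher in young and 2188 in old, and 337 were higher in both, against 85.0 for independent lists of these sizes. Of the 565 genes, 292 had a larger ratio in old mice and 125 were at least 2-fold lower there. Only 146 were at least 2-fold lower in young and 4727 in old, with 59 in both against 47.4, and 35 of the 146 were at least 2-fold higher in old. Across these genes Pearson's r was 0.30 and Spearman's rho 0.19, where genes are not independent replicates.

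**Figure D3:**
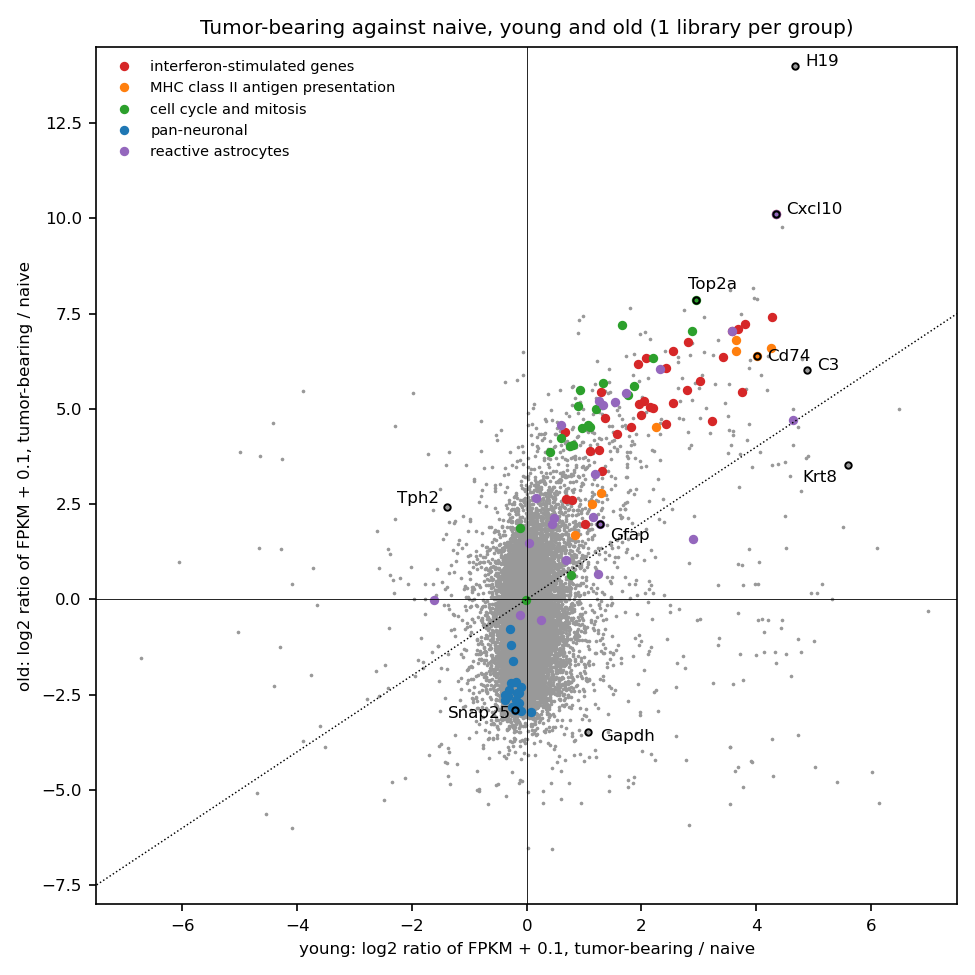
Log2 ratio of FPKM + 0.1, tumor-bearing to naive, in young (horizontal axis) and old (vertical axis) mice for the 14547 genes over the floor in both, 1 point per gene, with members of 5 gene lists in color, 10 genes labelled and a dotted line of equal ratios. Interferon-stimulated and MHC class II genes were higher in both and lay above the dotted line, while pan-neuronal genes were at least 2-fold lower in old mice only (17 of 18, against 0 of 18 in young), with medians of -2.48 and -0.22.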

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

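All tests of explanations in this part were chosen after the results were seen. The results listed here went at least 2-fold one way in 1 age or tumor state and the opposite way in the other, or, for gene lists, had medians of opposite sign and at least 1.5-fold from equal, and with 1 library per group these differences were not tested.

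Among the named genes, 3 had opposite directions of the tumor to naive ratio at the 2 ages. Tph2 had a log2 ratio of -1.39 in young and 2.42 in old tissue (difference 3.80), Avp of -2.30 and 2.11 (4.41), and Gapdh of 1.06 and -3.49 (-4.55), the last uncertain because of its pseudogenes.

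In the old to young ratio, the excitatory neuron median was 0.63 in naive and -2.03 in tumor-bearing tissue (difference -2.66), the striatum median 0.88 and -1.93 (-2.81), and the red blood cell median 0.59 and -0.89 (-1.48). Single genes of forebrain neurons went the same way, with differences of -3.88 for Cux2, -3.67 for Tbr1, -3.28 for Dlx6, -3.60 for Drd1, -3.02 for Rgs9, -2.75 for Adora2a, -3.10 for Ppp1r1b, -2.65 for Stx1a and -2.70 for Camk2a. So did the activity-related and clock genes Npas4 (-4.19), Egr4 (-3.73), Egr1 (-3.34), Arc (-2.84) and Per1 (-2.19), and Gapdh (-4.55). The opposite order, lower with age in naive and higher in tumor-bearing tissue, was found for Steap1 (difference 5.91), Cdc20 (5.52), Spp1 (4.89), Avp (4.41), the choroid plexus water channel gene Aqp1 (3.65), and the chaperone genes Hspa5 (2.69) and Sdf2l1 (2.53).

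The first pattern weighed is that of lower neuronal and higher cell cycle genes in the old tumor-bearing library. The deposited scaling is argued against as the whole cause, since the pan-neuronal median stayed at -1.91 when scaled by fragments in genes. For an even dilution of the same tissue by other cells, the oligodendrocyte median lay 1.98 above the pan-neuronal one. This argues against such dilution as the whole cause only if the added cells lacked oligodendrocyte RNA, which was not tested. Sox10, of that lineage, was 6.38-fold higher, but most oligodendrocyte genes were within 2-fold, so Sox10 does not speak for the list. Dilution by cells with such RNA stays open. A piece from another part of the brain and tumor tissue within the piece also stay open. A thalamus median 3.53 above the striatum median restates what was seen and decides nothing. The same holds for the 29 of 31 measured cell cycle genes at least 2-fold higher. Old against young naive tissue, which also differed in regional lists, had pan-neuronal and cell cycle medians of 0.21 and 0.05. H19 (2 and 142841 reads) and Y to X ratios at a median of 0.255 times those in old naive tissue go with tumor tissue if the grafted cells have such levels, which the sources used here did not give. Dividing immune cells could also raise cell cycle genes, and a response of old brain to a tumor, the biological explanation the design offers, stays open and was not tested.

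The second pattern is that of cerebellar genes near 0 in both old libraries. A general loss of neuronal RNA is argued against in the old naive library by the pan-neuronal median of 0.21 against young naive tissue. In the old tumor-bearing library neuronal RNA was broadly lower (pan-neuronal median -2.10 against young tumor-bearing tissue), and such a loss is argued against only as the whole cause, since the cerebellum median minus the pan-neuronal one was -2.92. The deposited scaling is argued against by a cerebellum median that stayed at -4.47 in old against young naive tissue when scaled by fragments in genes. Cerebellum left out of the old pieces stays open along with an untested effect of age on cerebellar cells, since the at least 13 of 14 members that were 2-fold or more lower in both age comparisons restate the pattern and would be found under either. However, the old naive library was also lower in the choroid plexus (median -2.66) and thalamus (-1.19) lists and higher in the striatum list (0.88). An effect of age on cerebellar cells alone leaves these differences unexplained. The choroid plexus list was not lower in old against young tumor-bearing tissue (median 0.11), so age alone does not account for it.

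The third pattern is that of higher MHC class II and complement genes in the young tumor-bearing library, where the deposited scaling is argued against by an MHC class II median of 2.99 when scaled by fragments in genes. A small share of tissue made up like the old tumor-bearing library is argued against as their whole cause, since the young difference was a median of 15.3% of the old one for MHC class II and 14% for complement genes, while cell cycle genes had 4.02% (middle 50% from 2.81% to 5.12%). For interferon-stimulated genes, with a share of 6.53%, such tissue stays open. Of 362 protein-coding genes outside the lists that were at least 10-fold higher in old tumor-bearing than in old naive tissue (median share 3.90%), 18, or 4.97%, had an upper 95% limit under 2.60%, which is 0.5 times the lower quartile of the interferon share. That is barely below the 5% set as the limit after these shares had been seen. The limit was a choice and not a rate expected from counting error, so the 4.97% decides nothing. Against such tissue, 10 of those genes had 0 reads in young tumor-bearing tissue and H19 had a share of 0.256%. A response of young brain to the tumor and cells that entered it may both contribute, and neither was tested.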

How the results depend on the processing

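The tests with scaling by fragments in genes, equal FPKM totals, protein-coding genes only and the exact interval were chosen after the data were seen, and the others before. Of 624 named-gene values at least 2-fold apart, all kept their sign in the 5331 recomputations, and 144 of these (85 values) came under 2-fold. The kept signs were largely fixed in advance and do not speak for robustness. A floor leaves the value of a gene unchanged, and a pseudocount cannot turn the sign of a ratio of 2 libraries. The scalings shifted the median of a comparison by at most 0.56, less than the log2 ratio of 1 required here. Of 107 list medians at least 2-fold apart, 945 of 949 recomputations kept the sign and 63 (23 medians) came under 2-fold. The 4 exceptions were B and plasma cells in old against young naive tissue (-0.11 with a floor of 0.1 FPKM, -0.00807 with no floor), the same list in the age by tumor difference (-0.68 with a floor of 5 FPKM) and chemokines in young tumor-bearing tissue (-0.0964 with that floor), where other members were measured. Medians nearer to 0 were less stable, and 31 of 121 under 2-fold changed sign under at least 1 of the 4 scalings, such as hypoxia and glycolysis in old against young tumor-bearing tissue (-0.13, or 0.26 under median-of-ratios scaling).

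Counts are given as higher and lower genes. They moved by over 1.5 times mostly with the floor, which sets how many genes enter. At 0.1 FPKM they were 3407 and 1626 for the tumor in young, 6262 and 8014 for the tumor in old, 3124 and 2729 for age in naive, 5545 and 8271 for age in tumor-bearing tissue, and 6419 and 9374 for the age by tumor difference. No floor gave the same counts except 6500 and 9518 for the last. At 5 FPKM they were 119 and 28, 1945 and 3240, 294 and 195, 1875 and 2900, and 1917 and 3295 in that order. A pseudocount of 1 FPKM gave 417 and 139 for the tumor in young and 528 and 422 for age in naive tissue. Protein-coding genes alone gave 298 and 45, and 415 and 391. The exact interval beyond 2-fold gave 222 and 20, and 279 and 286. Scaled by fragments in genes, the tumor in old gave 5366 and 3217, and the age by tumor difference 5226 higher genes. Equal FPKM totals gave 612 higher genes for age in naive tissue. The cause of these scaling effects was not tested. Counts not named here stayed within 1.5 times.

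Depth limits genes below about 0.2 FPKM, where few reads stand behind a value. The alternatives planned for replicates were not run. No paired analysis was possible because each group has 1 library.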

Other observations

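The tests and the genes of this part were chosen after the results were seen, and with 1 library per group no difference was tested between groups.

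Several granzyme genes of a cluster on chromosome 14 were present in the old tumor-bearing library and nearly absent elsewhere. Gzmc was at 17.6 FPKM, Gzmd at 21.5, Gzme at 9.53, Gzmf at 25.6 and Gzmg at 26.0, and the neighbouring mast cell protease gene Mcpt2 at 9.48 FPKM, with at most 1 read each in any other library. Their sequences are close, so the division of reads among them is uncertain.

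H19 was at 2497 FPKM in the old tumor-bearing library and 6.54 FPKM in the young one, against 0.159 and 0.052 FPKM in the naive libraries. Igf2, its imprinted neighbour, stayed at 0.12 to 0.288 FPKM in all 4. In the same library Sox10 was at 156 FPKM against 24.5 in old naive tissue, Nes at 22.0 against 3.58, and Vim at 347 against 10.1, while the fixed astrocyte identity, oligodendrocyte precursor and oligodendrocyte lists had medians of -1.59, -1.11 and -0.50. Trp53 was at 29.1 against 7.36 FPKM and Myc at 21.0 against 1.48. Of 75 measured ribosomal protein genes 49 were at least 2-fold higher and 2 lower (median log2 ratio 1.13), while in young tissue the median was -0.07.

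In the young tumor-bearing library, Krt8 (23.1 FPKM) and Epcam (3.21) were higher than elsewhere, and Krt18, the usual partner of Krt8, was 4.0-fold higher than in young naive tissue. Krt19 and Cldn4 had 0 reads there and Cldn7 had 1 read.

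Y-linked genes were low against their X-linked partners in the old tumor-bearing library. The ratio of Ddx3y to Ddx3x was 0.264 times that in old naive tissue (0.234 to 0.297), Eif2s3y to Eif2s3x 0.179 times (0.155 to 0.206), Kdm5d to Kdm5c 0.246 times (0.207 to 0.291) and Uty to Kdm6a 0.387 times (0.304 to 0.493), with a median of 0.255. In young tissue the pairs went both ways, in the same order 0.981 times (0.904 to 1.06), 1.37 times (1.23 to 1.53), 1.0 times (0.887 to 1.13) and 0.834 times (0.706 to 0.985). RNA from cells that do not express Y-linked genes may be a part of this, but the ratios are the pattern itself and do not test it. The low Xist level (4 reads) gives no sign of female mouse tissue, and the sex of the mice and of the cell line was not given in the sources used here. A lower ratio per cell would look the same, so the source stays open.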
